A study of Rattus norvegicus with 16 samples.

How the data were processed

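Total RNA from rat retina and pineal gland was profiled on 16 Affymetrix arrays with 8799 probe sets each. Per the labels, 12 arrays are retina and 4 are pineal, and each is titled with an hour, 6 or 12, in Zeitgeber time (ZT) or circadian time (CT). ZT conventionally counts hours from lights on under a light-dark cycle and CT counts hours of the internal clock without one, but the labels do not describe the lighting. The retina has 3 arrays for each of ZT6, ZT12, CT6 and CT12, numbered 1 to 3 in the titles, and the pineal has 1 array for each of these conditions. The labels do not say whether the numbered arrays come from separate animals, so p-values measure the spread between these samples.

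The deposited values are linear intensities with nearly the same trimmed mean on each array. With 2% of probe sets trimmed at each end, that mean lies between 2503 and 2506 on all arrays. The summarization software, the background correction and the scaling method are not given in the sources used here. Of the 8799 probe sets, 59 are controls. Among the other 8740, 7006 carry 1 gene symbol in the annotation, 308 carry several and 1426 carry none, which leaves 4736 named genes. Array data give no counting depth, and the number of arrays limits the precision.

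Median intensities of the retina arrays ranged from 671.3 to 858.4, more than 10% apart, so the 12 retina arrays were quantile normalized, and all 16 arrays for the tissue comparison. The 4 pineal arrays alone had medians of 531.6 to 576.3 and were compared as deposited. Values were transformed as log2 of the intensity plus 16. Probe sets were kept when their mean reached the 40th percentile, which left 5244 of them, with a lower limit of 8.88 log2 units in the retina and 8.81 in the tissue comparison. These covered 3173 genes in the retina fit and 3172 in the tissue fit.

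Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) after preparation in Python 3.11.15. One fit of the 4 retina groups, with 8 residual degrees of freedom and 2.54 prior degrees of freedom, gave 7 retina comparisons. These were ZT12 against ZT6, CT12 against CT6, CT6 against ZT6, CT12 against ZT12, hour 12 against hour 6 over both regimes, CT against ZT over both hours, and the difference between the time effects. The tissue comparison fitted tissue and condition to all 16 arrays, with 11 residual degrees of freedom. P-values were adjusted by Benjamini and Hochberg over the 5244 probe sets, with a threshold of 0.05, and errors on differences are standard errors. Single pineal arrays were compared without a test, by log2 differences of at least 1 in the same direction under ZT and CT.

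Gene groups came from 23 lists of clock, melatonin, immediate early, retinal cell type, lens, blood, immune, vascular and metabolic genes. Lists with at least 4 genes past the filter were tested with camera from limma, on the brightest probe set per gene, with a preset correlation of 0.01 between genes and again with a correlation estimated per list. Lists tested were 20 in the retina and 19 in the tissue comparison; the cone, bipolar cell and vascular lists were too small in both, and the pigment epithelium list in the latter. Named genes follow a rule. Up to 10 higher and 10 lower genes with the largest differences were taken among those that passed without overlap between the groups' arrays. Where fewer than 10 passed, the 5 higher and 5 lower genes with the smallest p were added as values that did not pass. For the tissue comparison the rule took 15 in each direction. Clock, clock output and melatonin genes that passed the filter were always included, with up to 4 members of other lists. The Nptx2 probe set was named outside this rule, after its values were seen. The comparisons, the lists, the rule and the alternatives were set before the data were examined, except where the text says otherwise.

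The procedure was tested in a single run on simulated data with the spread of the retina arrays. Probe sets were drawn independently, with the same spread in every group. In a comparison of 3 against 3 arrays it recovered 50 of 100 probe sets changed 2-fold and 76 of 100 changed 4-fold, with 3 false calls. In the tissue design it recovered 77 and 91 of 100, with 10 false calls. With nothing changed it made 0 limma calls, and among 19 simulated lists it called the 1 that had been shifted by 0.5 log2 units. It could not test the preset correlation where genes of a list vary together, as in the rod and lens lists (estimated correlation 0.927 and 0.867). Nor could it test the effect of a wider spread in the CT12 group.

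Alternatives tried were offsets of 1 and 64, the values as deposited, a common median, no filter, a filter at the 60th percentile, a trended robust prior, array weights, the title number as a replicate block, the arrays compared alone, the arrays numbered 3 left out together, and each array of the compared groups left out in turn. For the gene lists, the mean of all probe sets per gene was also used, and for the tissue comparison, tissue alone and hour 6 for the pineal array with conflicting labels. The titles carry a retina source name on every array, the pineal ones included, although they go on to name the pineal. This source name is "brain, retina" for the number-3 retina arrays and the pineal ZT12 array, and "eye, retina" for the others. The pineal array titled ZT12 carries 6 h in its description, and its title was used. Leaving out CT12 array 1 where it is not among the compared arrays, or from the list tests, leaving single retina arrays out of the tissue comparison, and a fit with the lens gene level of each array as a covariate, were chosen after seeing the data.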

Results

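Gene expression was measured in 12 rat retina arrays, 3 each at ZT6, ZT12, CT6 and CT12, and in 4 pineal arrays, 1 per condition. The labels give an hour and a time scale for each sample and state no question; the design separates the effect of the hour under each regime, the effect of the regime at each hour, and the difference between tissues. The trimmed mean intensity was nearly equal on all arrays, between 2503 and 2506, and the 50 brightest probe sets held 17.29% to 19.53% of the signal on 10 retina arrays.

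The CT12 array 1 stood apart from the other retina arrays. Its median Spearman correlation with the other 11 was 0.699, against 0.918 to 0.954 for the rest. Its 50 brightest probe sets held 28.37% of the signal, and those of CT12 array 2 held 22.66%. On this array the rod genes had a median deviation of -3.42 log2 units from the other 11 arrays, the ganglion cell genes -2.85 and the synaptic vesicle genes -1.94. The median spread within the CT12 group was 0.413 log2 units (SD, n = 3), against 0.17 to 0.201 in the other groups. Lens genes also varied between arrays. The mean level of 12 lens genes was 13.74 ± 1.99 at ZT6, 13.85 ± 2.25 at CT6, 15.04 ± 1.04 at ZT12 and 16.58 ± 0.91 at CT12 (log2, SD, n = 3). The highest single levels were 17.17 on CT12 array 1 and 17.02 on CT12 array 2, against 15.53 on CT12 array 3. CT12 array 2 was also the array that correlated best with CT12 array 1 (Spearman 0.819).

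**Figure D1:**
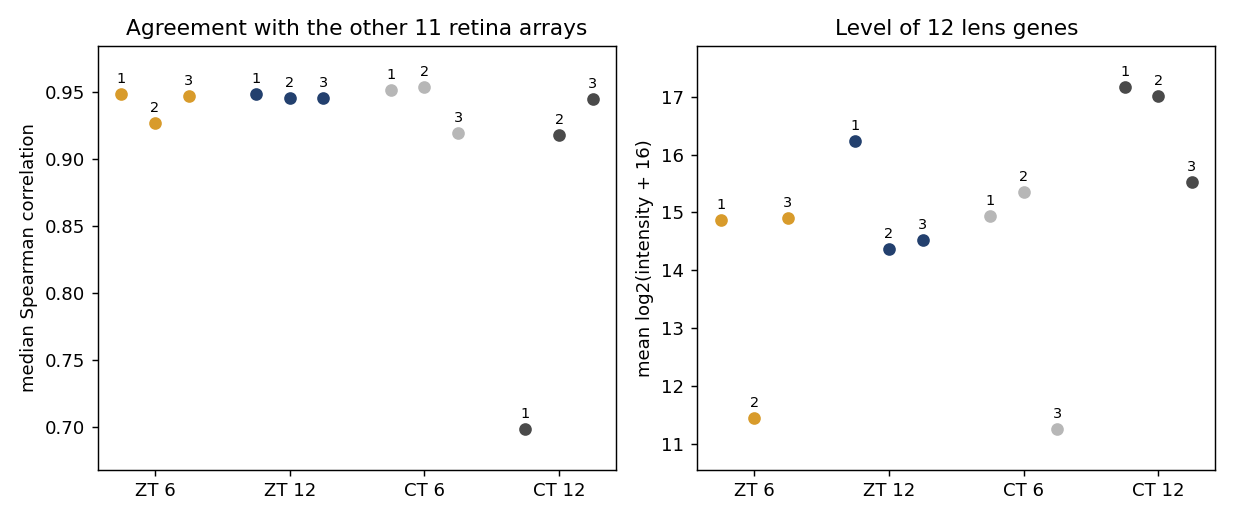
Left, median Spearman correlation of each retina array with the other 11; right, mean log2 intensity of 12 lens genes, with points numbered by array within the ZT6, ZT12, CT6 and CT12 groups. CT12 array 1 lies at 0.699 and the rest at 0.918 to 0.954.

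Under Zeitgeber time, the retina at hour 12 had far more transcript of the immediate early transcription factors Egr1 and Fos than at hour 6. Egr1, an activity-induced zinc finger factor, was 50-fold higher, at 16.76 ± 0.30 against 11.12 ± 0.19 (log2 intensity, SD, n = 3), with all 3 ZT12 arrays above all 3 ZT6 arrays. Fos, a component of the AP-1 transcription factor, was 3.71-fold higher, at 13.24 ± 0.10 against 11.35 ± 0.22. The mitochondrial carrier Slc25a30 was 3.87-fold higher, the lysosomal ganglioside activator Gm2a 2.65-fold higher and the heparan sulfate sulfotransferase Hs6st1 2.15-fold higher. Limk2, a kinase that acts on cofilin and the actin cytoskeleton, was 2.29-fold lower.

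In limma, 14 probe sets were higher and 1 was lower at ZT12 than at ZT6, for 10 named genes, and 452 had an unadjusted p under 0.05 against 262 by chance. Egr1 differed by 5.64 ± 0.68 log2 units (adjusted p = 0.0111), Fos by 1.89 ± 0.18 (adjusted p = 0.00279), Gm2a by 1.41 ± 0.24 (adjusted p = 0.0461), Hs6st1 by 1.10 ± 0.19 (adjusted p = 0.0484) and Limk2 by -1.20 ± 0.19 (adjusted p = 0.0461). The 95% interval of the Egr1 difference ran from 17.5-fold to 143-fold, and 3 of its 4 probe sets passed. Values that did not pass included 1.01 for the prolyl hydroxylase subunit P4ha1, 2.24 for Gstk1, 0.89 for Crot, 1.06 for Sdc4 and 1.28 for the cell cycle inhibitor Cdkn1a. On the lower side they were -2.43 for the cationic amino acid transporter Slc7a1, -0.96 for Pdzd11, -1.09 for Ints13, -0.92 for Bud31 and -1.74 for Tars1.

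The immediate early list rose at ZT12 with a preset correlation (median 0.21, 10 of 16 genes positive, adjusted p = 0.00467), with adjusted p = 0.0848 with an estimated correlation. Among its genes 2 rose over all genes tested and 4 when adjusted over the list alone. The nuclear receptor Nr4a1 differed by 2.33 ± 0.84 (adjusted p = 0.423), Junb by 1.35 and Klf10 by 1.03, while 6 of the 16 genes had negative differences. Genes of the list known to be induced at night in the pineal had a median of 0.35 (adjusted p = 0.00858, and adjusted p = 0.148 with an estimated correlation). As written, that list shares Egr1, Nr4a1, Crem, Fosl2 and Sik1 with the immediate early list, so it is not a separate result. Of its genes 1 rose over all genes tested, and its mean was 1.17. All 12 lens genes had positive differences (median 1.30, adjusted p = 0.00858, and adjusted p = 0.793 with an estimated correlation). The lists of blood genes (median -0.63, adjusted p = 0.0306), clock output genes (median -0.24, adjusted p = 0.0374) and ribosomal proteins (median -0.15, adjusted p = 0.0306) were lower. With an estimated correlation these 3 had adjusted p = 0.538, adjusted p = 0.751 and adjusted p = 0.821.

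The number of probe sets that passed depended on single arrays. CT12 array 1 enters this comparison only through the normalization, the filter and the spread. The filter was redone without it, here and below, so some lists then held other genes. The synaptic vesicle list, for example, had 13 genes in place of 12, and the immune list 8 in place of 9. Without this array 79 passed, 48 higher and 31 lower, among them all 15 of the above. Nr4a1 (2.33 ± 0.19, adjusted p = 0.000274), Junb (1.35, adjusted p = 0.0251), the dopamine receptor Drd4 (1.06, adjusted p = 0.0225) and Rorb (1.22, adjusted p = 0.0385) then rose. The immediate early and pineal night-induced lists each had adjusted p = 0.0474 with an estimated correlation. The immediate early and night-induced lists share genes, so these are not separate results. The blood list then did not pass with the preset correlation (adjusted p = 0.053). Without ZT6 array 1 or ZT12 array 1 the count was 6, and without any 1 of ZT6 arrays 2 and 3 or ZT12 arrays 2 and 3 it was 1; Fos passed in each case, Egr1 had adjusted p of 0.0626 to 0.101 in the latter 4, Slc25a30 of 0.066 to 0.105, and Gm2a (0.0501 to 0.298), Hs6st1 (0.066 to 0.325) and Limk2 (0.083 to 0.276) failed without any 1 of the 6 arrays. Without all arrays numbered 3 the count was 0 (Fos adjusted p = 0.0685, Egr1 adjusted p = 0.168), and with the lens gene level of each array as a covariate it was 3.

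**Figure D2:**
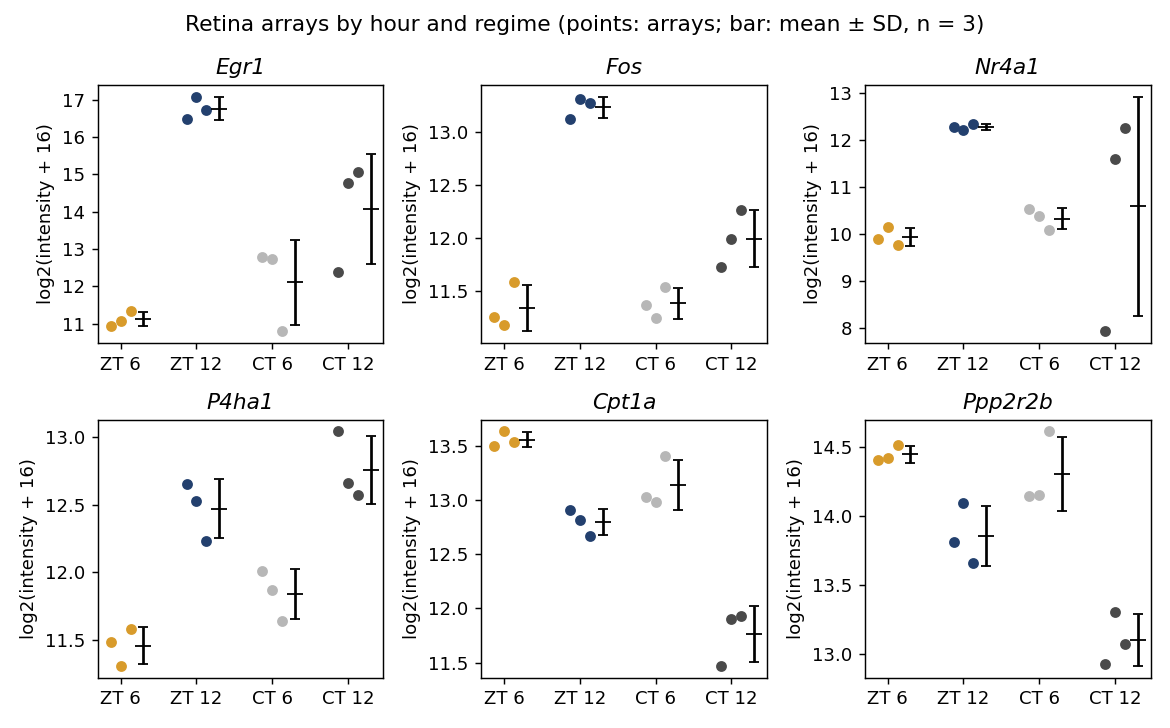
Log2 intensity plus 16 of Egr1, Fos, Nr4a1, P4ha1, Cpt1a and Ppp2r2b in each retina array at ZT6, ZT12, CT6 and CT12 (points), with the mean and SD of the 3 arrays (bars). Egr1 lies at 16.76 ± 0.30 at ZT12 and 11.12 ± 0.19 at ZT6.

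Under circadian time, the retina at hour 12 had less transcript of Cpt1a, the enzyme that admits long-chain fatty acids to mitochondrial oxidation, than at hour 6. Cpt1a was 2.59-fold lower, at 11.76 ± 0.26 against 13.14 ± 0.23 (log2 intensity, SD, n = 3). A probe set of neuronal pentraxin 2, Nptx2, was also lower, by -2.31 log2 units. Egr1 differed by 1.97 ± 0.68 and Fos by 0.61 ± 0.18, in the direction seen under Zeitgeber time, and neither passed (adjusted p = 0.143 and adjusted p = 0.127).

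In limma, 2 probe sets were lower and 0 higher at CT12 than at CT6, while 1440 had an unadjusted p under 0.05. The fit took a shared spread for all groups, although the CT12 arrays varied more (median SD 0.413 against 0.17 to 0.201). Where a probe set varies so, p is too small in comparisons with CT12 and too large for ZT12 against ZT6. In the 6 arrays alone, 578 had an unadjusted p under 0.05 and 0 passed. In the main fit Cpt1a differed by -1.37 ± 0.17 (adjusted p = 0.023), lower in 3 of 3 arrays. Values that did not pass were 1.67 for the sulfotransferase Sult1a1, 0.93 for Fut1, 1.11 for Efna1, 1.79 for the platelet chemokine Pf4, 0.89 for Hfe, -1.20 for the phosphatase subunit Ppp2r2b (adjusted p = 0.0508), -0.94 for Scfd1, -0.73 for Prune2 and -0.92 for Med13l.

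With the preset correlation the lens (median 2.75, adjusted p = 0.00104), ribosomal (0.28, adjusted p = 0.00167) and immune lists (0.68, adjusted p = 0.0108) were higher at CT12, and the ganglion cell (-1.04, adjusted p = 0.0106), rod (-1.42, adjusted p = 0.0108) and synaptic vesicle lists (-1.01, adjusted p = 0.0108) were lower. Each of these 6 had adjusted p = 0.775 with an estimated correlation. No lens gene passed over all genes tested, and 4 did when adjusted over the list alone. On CT12 array 1 the rod, ganglion cell and synaptic vesicle genes lay below, and the ribosomal and immune genes above, every other retina array by list median. Without it the medians shrank to -0.33 for rods, -0.35 for ganglion cells, -0.24 for synaptic vesicles, 0.06 for ribosomal proteins, 0.39 for the immune list and 2.44 for the lens, with adjusted p of 0.00161 to 0.0467 at the preset correlation and of 0.477 to 0.797 at an estimated one. The immediate early list then passed at the preset correlation (median 0.30, adjusted p = 0.00854) but not at an estimated one (adjusted p = 0.204). The chaperone list had a median of -0.09 but a mean of 0.08.

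The count at CT12 against CT6 changed with single arrays. Without CT12 array 1 it was 7, with both probe sets above kept and Nr4a1 higher by 1.59 ± 0.21 (adjusted p = 0.0287) and Egr1 at 2.75 (adjusted p = 0.0798). It was 1302 without CT12 array 3, 5 without CT12 array 2, 1 without CT6 array 1 and 0 without CT6 array 2 (913 at an unadjusted p under 0.05 in limma). Leaving out CT12 array 3 kept arrays 1 and 2, the arrays highest in lens genes. Cpt1a did not pass without any 1 of the CT6 arrays (adjusted p = 0.0621 to 0.0871), nor without all arrays numbered 3 (-1.34, adjusted p = 0.134) or with the lens covariate (-1.20, adjusted p = 0.253). It also lost its call with no filter, in the 6 arrays alone and with the title number as a replicate block. Over all 18 alternatives its difference stayed between -1.52 and -1.17. The Nptx2 probe set did not pass without CT6 array 1 or 2, without all arrays numbered 3, with no filter, in the 6 arrays alone, or with the lens covariate. Scaling moved the median of all genes from -0.06 to -0.10 log2 units as deposited and to -0.11 at a common median.

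Over both regimes, Fos was 2.38-fold higher and P4ha1, a subunit of collagen prolyl hydroxylase, 1.95-fold higher at hour 12 than at hour 6. Cpt1a was 2.09-fold lower, Ppp2r2b, a neuronal subunit of protein phosphatase 2A, 1.86-fold lower, and the Mediator subunit Med13l 1.69-fold lower. For each of these genes all 6 arrays at hour 12 lay on one side of all 6 at hour 6. Egr1 was 14-fold higher and Slc7a1 4.32-fold lower, with some overlap between arrays.

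In limma, 6 probe sets were higher and 5 lower, for 7 genes. Fos differed by 1.25 ± 0.12 (adjusted p = 0.00531), P4ha1 by 0.96 ± 0.13 (adjusted p = 0.0131), Cpt1a by -1.07 ± 0.12 (adjusted p = 0.00958), Ppp2r2b by -0.89 ± 0.13 (adjusted p = 0.0179), Med13l by -0.76 ± 0.12 (adjusted p = 0.0363), Egr1 by 3.81 ± 0.48 (adjusted p = 0.0129) and Slc7a1 by -2.11 ± 0.31 (adjusted p = 0.0227). The lactate transporter Slc16a3 (0.79), Acaa2 (0.96), Slc25a30 (0.99), Sult1a1 (1.04), Limk2 (-0.77), Pde6d (-0.60), Scaf8 (-0.69) and Odf2 (-0.54) did not pass.

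The lens (median 1.89, adjusted p = 1.17e-05), immediate early (0.24, 11 of 16 positive, adjusted p = 0.00956) and immune lists (0.28, adjusted p = 0.043) were higher at hour 12 with the preset correlation, and the ganglion cell (-0.57, adjusted p = 0.043) and rod lists (-0.86, adjusted p = 0.0242) lower. With an estimated correlation the immediate early list had adjusted p = 0.151, the lens and immune lists adjusted p = 0.793, and the ganglion cell and rod lists adjusted p = 0.812. When CT12 array 1 was left out, the rod median was -0.24 (adjusted p = 0.00643) and the lens median 1.74 (adjusted p = 5.56e-05), while the ganglion cell (-0.23, adjusted p = 0.0573) and immune lists (0.18, adjusted p = 0.16) did not pass; with an estimated correlation the rod and lens lists then had adjusted p = 0.724. The mean lens level differed by 2.01 log2 units between hours (exact permutation p = 0.0584, two-sided).

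Leaving out arrays changed the count over both regimes. Without CT12 array 1 it was 68, 34 in each direction, with all 11 kept; Nr4a1 (1.96 ± 0.14, adjusted p = 0.000154), Rorb (1.16, adjusted p = 0.0142), the adrenergic receptor Adra1b (0.82, adjusted p = 0.0199), Drd4 (0.97, adjusted p = 0.0105) and the chaperone Hspa5 (0.50, adjusted p = 0.0142) rose, and the immediate early list had adjusted p = 0.0346 with an estimated correlation. The count was 3 without ZT6 array 1 or 2, 4 without ZT12 array 2, 5 without ZT6 array 3 or ZT12 array 3, and 176 without CT12 array 3; Fos and Cpt1a passed throughout, whereas Egr1 and P4ha1 did not without ZT6 array 1, ZT6 array 2 or ZT12 array 2 (adjusted p = 0.0525 to 0.0583), nor Ppp2r2b without any 1 of the ZT6 arrays or ZT12 array 3 (0.0579 to 0.086), nor Slc7a1 without any 1 of the ZT6 arrays, ZT12 array 2 or ZT12 array 3 (0.0663 to 0.0926). Med13l kept its call only without CT6 array 2, CT12 array 1 or CT12 array 3, with adjusted p = 0.0665 to 0.102 without any of the other 9. With the lens gene level of each array as a covariate 0 passed, Fos then at 1.31 (adjusted p = 0.0595) and Cpt1a at -0.94 (adjusted p = 0.137). Without all arrays numbered 3 also 0 passed, with Fos at 1.28 (adjusted p = 0.143).

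At hour 6, the retina under circadian time did not differ detectably from the retina under Zeitgeber time. The smallest p belonged to Gm2a, 3.01-fold higher at CT6 (1.59 ± 0.24, adjusted p = 0.147). Other values that did not pass were the kinase Mapk7 (1.64, adjusted p = 0.801), Slc16a6 (0.79), the respiratory chain genes Atp5pd (0.57) and Ndufb10 (0.65), Fut1 (-0.76), Aph1a (-0.88), Bloc1s2 (-0.56), Bud31 (-0.76) and Lrrc8a (-0.74). In limma 0 probe sets passed, and 266 had an unadjusted p under 0.05 against 262 by chance. The oxidative phosphorylation list was higher at CT6 with the preset correlation, with 36 of 52 genes positive (median 0.10, adjusted p = 0.0126, and adjusted p = 0.945 with an estimated correlation). Without CT6 array 3 the count was 3, all lower.

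At hour 12, the retina under circadian time had less Fos transcript than under Zeitgeber time, 2.36-fold less (n = 3 per group). A probe set of the glutathione transferase Gstk1 was 6.27-fold lower at CT12, while the other had the opposite sign. Slc25a30 was 3.87-fold lower, the peroxisomal carnitine transferase Crot 2.31-fold lower and Cpt1a 2.04-fold lower. The glycine transporter Slc6a5, used by glycinergic neurons, was 2.99-fold higher and Slfn2 2.57-fold higher. Slc6a5 was dim enough to fall below the filter in some alternatives, so the size of its ratio is uncertain too.

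In limma, 6 probe sets were higher and 26 lower at CT12, for 25 genes. Slc6a5 differed by 1.58 ± 0.22 (adjusted p = 0.0216), Slfn2 by 1.36 ± 0.21 (adjusted p = 0.0319), Gstk1 by -2.65 ± 0.41 (adjusted p = 0.0319), Fos by -1.24 ± 0.18 (adjusted p = 0.024) and Cpt1a by -1.03 ± 0.17 (adjusted p = 0.0358). Cyp2e1 (0.93) and Cyss (0.92) also rose, and Scfd2 (-1.59), Cdkn1a (-1.57), Mtfr1 (-1.15), Dync1h1 (-1.15) and Hs6st1 (-1.04) fell. Of the 2 Gstk1 probe sets 1 passed and the other had the opposite sign. Egr1 differed by -2.69 and did not pass (adjusted p = 0.107).

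With the preset correlation 6 lists were higher at CT12, namely ribosomal proteins (median 0.34, 37 of 40 positive, adjusted p = 1.31e-06), blood (1.23, adjusted p = 0.00483), immune (0.42, adjusted p = 0.0451), lens (1.51, adjusted p = 0.042), oxidative phosphorylation (0.16, adjusted p = 0.042) and the pigment epithelium (0.94, adjusted p = 0.0457). The ganglion cell (-1.15, adjusted p = 0.00582), rod (-1.23, adjusted p = 0.042) and synaptic vesicle lists (-0.99, adjusted p = 0.00254) were lower. With an estimated correlation the lens and rod lists had adjusted p = 0.641 and the other 7 adjusted p = 0.619. No ribosomal protein gene passed over all genes tested, and 4 did when adjusted over the list alone. On CT12 array 1 the rod, ganglion cell and synaptic vesicle genes lay lowest and the ribosomal and immune genes highest. Without it the rod (-0.05, adjusted p = 0.98), lens (1.24, adjusted p = 0.0796) and immune lists (0.21, adjusted p = 0.228) did not pass. The ribosomal (0.20, adjusted p = 9.01e-05), blood (1.15, adjusted p = 0.00534), synaptic vesicle (-0.34, adjusted p = 0.00534), ganglion cell (-0.34, adjusted p = 0.00839), oxidative phosphorylation (0.09, adjusted p = 0.0166) and pigment epithelium lists (1.06, adjusted p = 0.044) still did with the preset correlation, and each of these 6 had adjusted p of at least 0.413 with an estimated one.

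Without CT12 array 1, 32 probe sets passed, 4 higher and 28 lower, of which 17 were shared; Cyp2e1, Cyss, Cdkn1a, Mtfr1 and Hs6st1 then did not pass (adjusted p = 0.0504 to 0.0586). The count was 1069 without CT12 array 3, 19 without CT12 array 2, 2 without ZT12 array 1, and 0 without ZT12 array 2 or without ZT12 array 3 (813 and 987 at an unadjusted p under 0.05 in limma), and each of the genes named above as past the threshold lost its call without any 1 of the ZT12 arrays. Gstk1, Scfd2, Cdkn1a, Crot, Hs6st1 and Cpt1a also lost theirs without CT12 array 2 (adjusted p = 0.0575 to 0.0783). None of the named genes passed in 3 other settings, in which the count was 2 with the lens covariate, 0 in the 6 arrays alone, and 1, not among the 32, without all arrays numbered 3. Their differences changed less than their p. Over all alternatives Fos stayed between -1.41 and -1.09, the Gstk1 probe set that passed between -2.96 and -2.41 and Slc25a30 between -2.19 and -1.77. With the lens covariate they were at -1.19, -2.87 and -1.98.

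Averaged over both hours, no gene separated the retina under circadian time from the retina under Zeitgeber time. The values with the smallest p were 0.92 for Slc6a5 (adjusted p = 0.202), 1.82 for the retinoid isomerase Rpe65, 0.56 for Ndufb10, 0.76 for Rin1, -0.64 for Wbp11, -0.72 for Cpt1a, -0.99 for Slc25a30, -0.51 for Acy1 and -0.46 for Bloc1s2. In limma 0 probe sets passed and 620 had an unadjusted p under 0.05. With the preset correlation 5 lists were higher, ribosomal (0.21, adjusted p = 1.7e-05), oxidative phosphorylation (0.13, adjusted p = 0.00061), blood (0.76, adjusted p = 0.0036), pigment epithelium (0.49, adjusted p = 0.0217) and lens (0.81, adjusted p = 0.0328). The ganglion cell (-0.57, adjusted p = 0.0161) and synaptic vesicle lists (-0.50, adjusted p = 0.00928) were lower. With an estimated correlation the first 5 had adjusted p from 0.703 to 0.714, and the last 2 had 0.709 and 0.714. Of these 7 lists 5 still passed without CT12 array 1; the ganglion cell median was then -0.17 (adjusted p = 0.025) and the ribosomal median 0.10 (adjusted p = 0.00173), and the synaptic vesicle (-0.14, adjusted p = 0.0587) and lens lists (0.67, adjusted p = 0.0735) did not pass. Each of the 5 then had adjusted p = 0.503 with an estimated correlation. Without CT12 array 2 the count was 3, without CT12 array 3 it was 2, and without CT6 array 3 it was 1.

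The difference between regimes in the effect of the hour was tested directly. A single probe set passed, for Nptx2, a secreted synaptic protein, which was higher at hour 12 under Zeitgeber time (1.63) and lower under circadian time (-2.31). Its group means were 9.89 at ZT6, 11.52 at ZT12, 11.64 at CT6 and 9.33 at CT12, a difference of -3.95 between the time effects (adjusted p = 0.00399 in limma). The other Nptx2 probe set gave -1.44. Fos rose less under circadian time by point estimate, but the difference of -1.28 ± 0.25 did not pass (adjusted p = 0.115), nor did -3.68 ± 0.97 for Egr1 (adjusted p = 0.205), -4.16 for Gstk1 (adjusted p = 0.0587), -2.54 for Cdkn1a, -1.87 for Gm2a, -1.92 for Slc25a30, -1.49 for Slc16a6, 1.28 for Fut1, 1.45 for Aph1a, 1.51 for Slfn2, 1.30 for Rgs14 or 1.12 for Cyp2e1.

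Lists that passed for this difference with the preset correlation were ribosomal (0.35, adjusted p = 7.02e-05), blood (0.94, adjusted p = 0.0349) and immune (0.74, adjusted p = 0.0426) on the higher side, and synaptic vesicle (-1.10, adjusted p = 0.00859) and ganglion cell (-1.22, adjusted p = 0.0276) on the lower. Each of these 5 had adjusted p = 0.724 with an estimated correlation. Only the ribosomal (0.19, adjusted p = 0.00339) and synaptic vesicle lists (-0.42, adjusted p = 0.0126) passed without CT12 array 1, with the ganglion cell list at -0.39 (adjusted p = 0.0709), blood at 0.85 (adjusted p = 0.0709) and immune at 0.47 (adjusted p = 0.155). With an estimated correlation the ribosomal and synaptic vesicle lists then had adjusted p = 0.584 and adjusted p = 0.542. Across all probe sets, which are not independent replicates, the time effects under the 2 regimes had a Pearson r of 0.166 and a Spearman correlation of 0.057, and 51.4% had the same sign; 10 of the 15 probe sets that passed under Zeitgeber time had the same direction under circadian time. The count for this difference was 62 without CT12 array 3, 4 without CT12 array 2, 3 without CT6 array 1, and 2 without ZT6 array 1 or CT6 array 2.

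Clock genes in the retina did not pass over all genes tested with all arrays included. Of the 17 core clock genes listed, 7 were on the array and 6 passed the filter. When adjusted over the list alone, Csnk1d (0.65), Per2 (0.74) and Nr1d1 (-0.53) passed at CT12 against CT6 (adjusted p = 0.0461 each), and Per2 (adjusted p = 0.0333) and Bhlhe41 (adjusted p = 0.0164) over both regimes. These list-alone calls include CT12 array 1 and were not repeated without it. On that array the core clock genes had a median deviation of -0.64 (others -0.18 to 0.31). Over both regimes, hour 12 minus hour 6 was 0.66 ± 0.19 for Per2, a core repressor of the clock (adjusted p = 0.188), 0.32 for Csnk1d, -0.30 for Nr1d1, -1.26 ± 0.71 for Bmal1 (adjusted p = 0.351), -0.20 for Nr1d2 and 0.44 for Rorb. The Bmal1 and Rorb values rested on CT12 array 1, at 7.48 and 8.43 where the other CT12 arrays had 11.93 and 12.56 for Bmal1 and 12.75 and 12.88 for Rorb. Without it Bmal1 was at -0.46 (adjusted p = 0.194) and Rorb at 1.16 (adjusted p = 0.0142), past the threshold. Clock output genes were at -0.54 for Bhlhe41 (adjusted p = 0.169), -0.43 for Dbp, -0.41 for Bhlhe40, -0.20 for Hlf and 0.02 for Tef, and without that array at -0.41 for Bhlhe41, -0.20 for Dbp, -0.20 for Bhlhe40, -0.18 for Hlf and 0.05 for Tef. Nr1d1 was then at -0.19, Nr1d2 at -0.12, Csnk1d at 0.23 and Per2 at 0.49 (adjusted p = 0.0817). Under Zeitgeber time all 5 clock output genes had negative differences, from -0.58 for Hlf to -0.17 for Dbp. The core clock list had a median of -0.04 there, a mean of 0.21 and a test pointing up (adjusted p = 0.534).

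Of the 11 genes of melatonin synthesis and indole metabolism on the array, only 5 passed the filter in the retina. Aanat, Asmt, Tph1 and Ddc were not among them, so these enzymes were not tested there. The 5 genes did not pass over all genes tested either with all arrays included, and 1, Adra1b, did when adjusted over the list alone. Over both regimes they were at 0.68 for Adra1b (adjusted p = 0.163), 0.34 for the tetrahydrobiopterin enzyme Gch1, -0.70 for Adrb1, 0.20 for Maoa and -0.20 for Maob (list adjusted p = 0.282). Dopamine genes had a median of -0.19 (adjusted p = 0.734). Lists of retinal glia (-0.20, adjusted p = 0.98), amacrine cells (-0.41, adjusted p = 0.157), sterol synthesis (0.10, adjusted p = 0.181), chaperones (0.02, adjusted p = 0.29) and glucocorticoid-responsive genes (0.01, adjusted p = 0.861) did not pass over both regimes. Cone opsins were at -0.10 for Opn1sw and -0.72 for Opn1mw, the bipolar cell genes Grm6 and Prkca at -0.47 and -0.31, and the vascular genes Flt1, Kdr and Pecam1 at 0.62, -0.56 and 0.20, none past the threshold. CT12 array 1 contributed much of several of these values. Without it Adra1b passed (0.82, adjusted p = 0.0199), and Adrb1 was at -0.22, Opn1mw at -0.46, Grm6 at -0.09, Prkca at -0.16, Kdr at -0.22, Flt1 at 0.46 and Pecam1 at 0.44, while Opn1sw changed sign to 0.19. The medians for retinal glia, amacrine cells and sterol synthesis were then -0.02, -0.14 and -0.01.

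The pineal gland differed from the retina in most genes measured. Gch1, which makes the cofactor of tryptophan hydroxylase, was 210-fold higher in the pineal, and Asmt, the last enzyme of melatonin synthesis, 28.9-fold higher. Monoamine oxidase Maob was 23.6-fold higher, the lipoprotein lipase Lpl 61.9-fold, the IgE receptor chain Fcer1a 38.8-fold and the potassium channel Kcnh6 34.8-fold. The retina had more aldolase, Aldoa by 411-fold and Aldoc by 51.5-fold, more of the vesicle fusion factor Nsf (99.7-fold) and more gamma-synuclein, Sncg (62.8-fold). The lens crystallins Crygc and Cryba4 were 279-fold and 190-fold lower in the pineal. The mean lens level ranged from 11.26 to 17.17 log2 units between retina arrays. For lens genes, here and below, a tissue difference was therefore not separated from lens tissue in the retina samples.

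In limma 2066 probe sets were higher and 1913 lower in the pineal, 2735 of them at least 2-fold apart, for 2525 genes. With no filter 3019 were higher and 2320 lower. All 4 pineal arrays lay on one side of all 12 retina arrays for each gene named above. In the dimmer tissue many of these genes lay below the filter limit of 8.81, among them Crygc (6.40), Nsf (6.91), Aldoa (7.20), Sncg (7.76) and Cryba4 (8.16) in the pineal and Fcer1a (8.30), Gch1 (8.36) and Asmt (8.57) in the retina. No background was measured, so the size of such ratios is uncertain. Gch1 differed by 7.71 ± 0.26 (adjusted p = 7.39e-12) and Aldoa by -8.68 ± 0.43 (adjusted p = 3.05e-10). Other genes higher in the pineal were Tc2n (44.8-fold), Cd1d1 (38.4-fold), Itpr1 (27.1-fold), Ak4 (25.0-fold), Cacna2d1 (24.0-fold), Nptx1 (23.9-fold), Padi4 (23.1-fold), Prickle2 (22.9-fold) and Ccdc141 (22.8-fold). Others lower were Cryba1 (164-fold), Ass1 (124-fold), Crybb1 (94.9-fold), Crybb2 (86.8-fold), Grifin (82.4-fold), Crybb3 (81.3-fold), Ntm (76.7-fold), Fez1 (53.7-fold) and Sptan1 (51.7-fold), and of these only Crybb2 (10.52) and Crybb3 (9.52) reached the limit in the pineal. Among the higher ones Tc2n (7.99), Padi4 (8.03), Ccdc141 (8.46), Nptx1 (8.59) and Cd1d1 (8.63) lay below it in the retina.

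Genes of amacrine cells were lower in the pineal (median -1.19, adjusted p = 0.00565, and adjusted p = 0.797 with an estimated correlation), where 8 of 13 fell and 1 rose. The GABA transporter Slc32a1 differed by -4.94 and Gad1 by -4.83. The lens list (-6.01, adjusted p = 0.00188), where 10 of 12 genes fell and 11 when adjusted over the list alone, and the ribosomal list (-0.71, 26 of 40 fell, adjusted p = 0.000312) were lower too. With an estimated correlation these 2 also had adjusted p = 0.797. Among rod genes 5 of 10 fell and 2 rose (median -1.32, adjusted p = 0.21), with Prph2 at -4.61 and Sag at -3.92. The sterol enzymes Fdps (-5.20) and Fdft1 (-4.93) fell within a list that did not pass (median -0.76, adjusted p = 0.0907). The chaperones Hsph1 (3.20), Hspe1 (2.87) and Hspd1 (2.41) rose and Fkbp4 (-2.23) fell.

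Clock and receptor genes differed between the tissues as well. Nr1d1 (-1.66) and Tef (-1.09) fell and Nr1d2 (1.04), Bhlhe41 (1.32) and Hlf (0.58) rose, while Per2 (-1.03, adjusted p = 0.0999), Bhlhe40 (-0.51), Dbp (0.35), Rorb (0.30), Csnk1d (-0.10) and Bmal1 (-0.05) did not pass. Adra1b was higher in the pineal (2.24) and Adrb1 (-3.56) and Maoa (-0.91) were lower. Quantile normalization assumes similar distributions in both tissues, and with the values as deposited 1621 probe sets were higher and 2279 lower, with the median of all genes at -0.23 in place of 0.09 log2 units. The fit assumes that the condition acts alike in both tissues. The filter took the mean over 12 retina and 4 pineal arrays, so genes bright only in the pineal could fall below it. Aanat, Tph1 and Ddc were not among the 6 genes of the melatonin list tested between the tissues.

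Within the pineal, with 1 array per condition and no test, hour 12 showed higher values of most genes known for night-time induction under both regimes. The peptide transporter Slc15a1 had 4362 intensity units at ZT12 against 40 at ZT6, and 8888 at CT12 against 19 at CT6. Its hour 6 values lie so near the offset of 16 that the ratio is not determined; with an offset of 64 the differences were 5.41 and 6.76 log2 units. Aanat, the enzyme that sets the rhythm of melatonin synthesis, was 21.3-fold and 44.8-fold higher. Fcer1a was 15.8-fold and 14.3-fold higher, the phosphatase Dusp1 9.14-fold and 10.5-fold, Nr4a1 9.25-fold and 8.05-fold, and Drd4 4.96-fold and 8.86-fold.

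In total 80 probe sets were at least 2-fold higher and 54 lower at hour 12 under both regimes, and 24 went in opposite directions. Across the 5244 probe sets the differences had r = 0.393. Fhip2a (4.60-fold and 5.44-fold), Bend3 (4.71-fold and 4.57-fold), Ptpn3 (2.09 and 2.32 log2 units) and Tc2n (4.87-fold and 4.17-fold) were also higher. Lower values were found for neurogranin, Nrgn (11.9-fold and 4.12-fold), the kinase Sgk1 (3.61-fold and 5.24-fold), Ptpn21 (4.23-fold and 3.63-fold), Nudt4 (8.38-fold and 3.29-fold), Faslg (6.14-fold and 3.32-fold), Slc6a13 (3.25-fold and 3.22-fold), RT1-A3 (3.20-fold and 3.64-fold), Mrps11 (3.33-fold and 3.21-fold), Ttll5 (2.98-fold and 3.26-fold) and Hes5 (2.97-fold and 3.30-fold). Apart from Sgk1 and Ptpn21, the hour 12 intensities of these genes were only 131 to 267, and no background was measured, so the size of these ratios is uncertain.

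The 12 measured pineal night-induced genes had a median difference of 1.48 log2 units under Zeitgeber time and 2.35 under circadian time. The deiodinase Dio2 had 838 intensity units against 271 under Zeitgeber time and 2451 against 54 under circadian time, the last too dim for a ratio. Higher too were Pde4b (2.61-fold and 3.21-fold), Egr1 (2.13-fold and 2.32-fold) and Crem (2.19-fold and 3.02-fold). Fosl2, of the same list, was 2.87-fold lower under Zeitgeber time (291 against 866 intensity units) and 1.11-fold higher under circadian time. Among core clock genes Rorb was 1.93-fold and 5.77-fold higher, Nr1d2 1.76-fold and 2.24-fold higher, and Bmal1 1.55-fold and 2.49-fold lower; the list median was 0.35 and 0.51. Dbp was 2.26-fold and 1.68-fold higher. Asmt (-0.16 and -0.40) and Tph1 (-0.55 and -0.33) differed little, and Fos was at -0.54 and -0.26. One array per condition gives no error for these values, and the ZT12 array has conflicting labels for its hour.

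**Figure D3:**
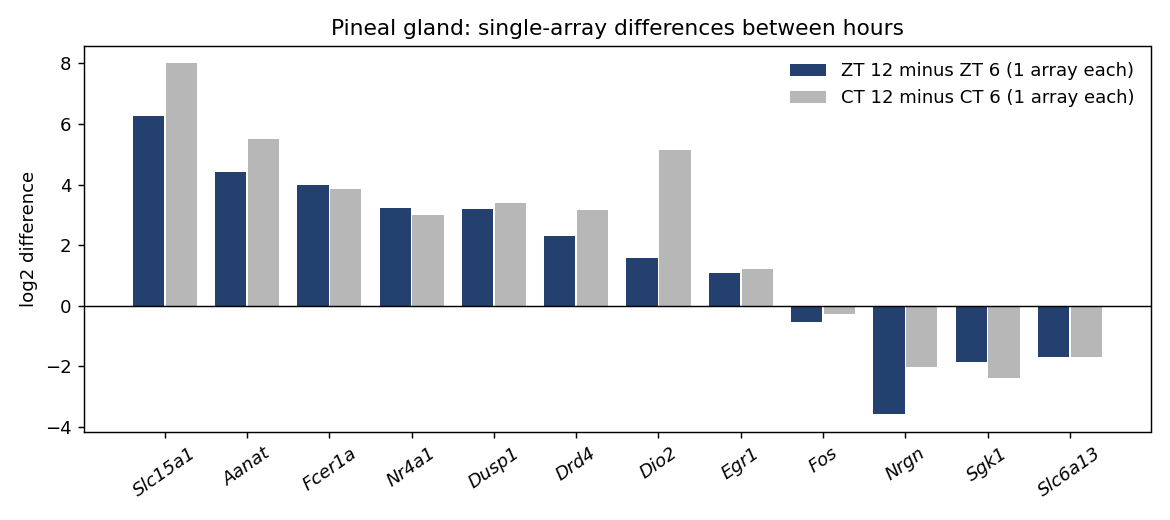
Log2 difference between hour 12 and hour 6 in single pineal arrays under ZT and under CT for 12 genes; each bar is 1 array minus 1 array, with no error. Aanat stands at 4.41 and 5.49, and Nrgn at -3.58 and -2.04.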

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

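The tests of pineal RNA, of lens in place of most of the retina, of lens tissue carried into the dissection, of chance in which arrays carry lens transcripts, and of other splits of the arrays were chosen only after the result was seen.

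CT12 array 1 correlated with the other retina arrays at 0.699, and its rod genes lay 3.42 log2 units below them by median (-3.42, lowest of the others -0.12). Its genes over 8-fold higher in pineal deviated by 0.26 (others -0.09 to 0.16) where pineal RNA would need about 3.48, and by 0.09 against 3.54 for the wider set of 76 genes as deposited. This argues against pineal RNA as the whole cause. The slope of all deviations on the tissue difference was 0.112 (others -0.038 to 0.032), however, past the bound set for pineal RNA. The bound on the deviations was added after these values were seen. It replaced an earlier bound that gave opposite answers for the 2 gene sets. RNA degradation stays open, since the mean excess of 3' over 5' signal of 3 control genes was 0.81 against 0.273 to 0.459. The control genes were not alike, however. GAPDH was at 0.72 and hexokinase at 1.24, but beta-actin at 0.46 lay below CT6 array 1 (0.5) and CT12 array 3 (0.54). Lens in place of most of the retina also stays open, since the lens fibre genes Mip, Lim2 and Bfsp1 were all highest here while rod genes were at -3.42. Lens tissue by the level of the lens list cannot be told apart from the rest, because the list deviated by 2.48 (highest other 2.49) on a scale that quantile normalization caps, with the lens genes at the 99.8th percentile, and as deposited it deviated by 3.48 (highest other 2.91). As deposited, Bfsp1, Lim2 and Mip were 76.6-fold, 34.1-fold and 27.3-fold above the mean of the other arrays. Dcn and Igf1, which are not in the lens list, were 101-fold and 23.3-fold above it, while Nefl and Sag were 39.3-fold and 19.5-fold below. The 3' excess does not address the higher values. The design gives no biological explanation for 1 array of a group, so none was tested, and degradation or a sample rich in lens may each contribute to it as hypotheses.

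Lens genes varied between retina arrays and were higher at hour 12 by 2.01 log2 units. The fibre genes Mip, Lim2 and Bfsp1 followed the crystallins within groups with a mean r of 0.81 over 12 arrays; their mean gave Pearson r = 0.83 (permutation p = 0.00052) and Spearman rho = 0.78 (permutation p = 0.00442), and r = 0.78 without the 2 arrays farthest from the median. Lens tissue carried into the dissection is a candidate explanation of this shared variation. The hour of the arrays gave an exact permutation p of 0.0584, two-sided, so chance in which arrays carry lens transcripts also stays open. A change of lens genes with the hour, which the design names, was not separated from either.

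Egr1 and Fos were higher at ZT12 than at ZT6. An offset of 64 left the smaller of their differences at 1.87. That test could hardly come out otherwise, because both genes were far brighter than the offset already at ZT6. Their ZT6 means of 11.12 for Egr1 and 11.35 for Fos, above the filter limit of 8.88, argue against a dim baseline. With the lens level of each array as a covariate the smaller difference was 1.93 (Fos adjusted p = 0.00993, and Egr1 5.47, adjusted p = 0.0474), which argues against lens tissue. Heat shock and handling stress cannot be told apart from an effect of the hour, because the median chaperone difference of 0.00067 comes from 7 genes above and 7 below 0. The prediction written in advance took a median under 0.1 as evidence against stress, and it was set aside because members moved both ways. An effect of time of day or of light at the moment of sampling may account for the difference as a hypothesis, untested here.

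The difference between regimes in the time effect of an Nptx2 probe set was -3.95 log2 units, marked because the test of the difference itself passed. Apart from the other splits of the arrays below, which left chance open, no explanation was tested.

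Other splits of the same arrays were counted for each comparison. For 3 against 3 arrays there are 10 splits, too few for a share under 0.05. As many limma calls as in the real split came in 1 of 10 for ZT12 against ZT6 (15, highest other 0) and 1 of 10 for CT12 against CT6 (2, highest other 0). For CT12 against ZT12 it was 1 of 10 (32, highest other 1). For CT6 against ZT6 the real count was 0 (highest other 0), so a share of 10 of 10 was fixed in advance. Over both regimes, 1 of 100 splits, the real split itself, gave as many calls for the hour (11, highest other 1). Random splits of these arrays thus did not reach the real count. They cannot separate the hour from the lens level, and 0 passed with the lens covariate or without all arrays numbered 3. For CT against ZT the real count was 0 (highest other 1), so a share of 100 of 100 was fixed in advance and says nothing about chance. For the difference between time effects 6 of 100 gave as many as the real 1 (highest other 2), so chance cannot be excluded. For pineal against retina 1 of 100, the real split itself, gave as many as the real 3979 (highest other 2075), so random splits did not reach that count.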

How the results depend on the processing

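The lens covariate, leaving out CT12 array 1 where it was not among the compared arrays or from the list tests, and leaving single retina arrays out of the tissue comparison were chosen only after the result was seen. Unless a reason is given, the cause of a change was not tested. Numbers are probe sets past the limma threshold; the main counts were 15 for ZT12 against ZT6, 2 for CT12 against CT6, 0 for CT6 against ZT6 (266 at an unadjusted p under 0.05), 32 for CT12 against ZT12, 11 for the hour over both regimes, 0 for CT against ZT (620), 1 for the difference between time effects and 3979 for tissue. With 3 arrays per group and no measure of background among the values, small differences in dim genes were not resolvable.

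An offset of 1 gave 5 for CT12 against CT6. Values as deposited gave 9 for ZT12 against ZT6 and 21 for CT12 against ZT12. A common median gave 9 for CT12 against CT6 and 72 for CT12 against ZT12, of these 5 higher and 67 lower, where the main split was 6 and 26. No filter gave 6 for ZT12 against ZT6, 0 for CT12 against CT6 (1717 at an unadjusted p under 0.05) and 3 for CT12 against ZT12 with more probe sets tested. The 60th percentile filter gave 8 for CT12 against CT6 and 21 for CT12 against ZT12, with fewer tested. For pineal single-array differences: probe sets at least 2-fold apart, same direction in both regimes, no filter gave 311 and the 60th percentile filter 74, in place of 134. Offset 64 and a trended robust prior left every count within 1.5 times the main one.

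Array weights gave 279 for ZT12 against ZT6, 2522 for CT12 against CT6, 3 for CT6 against ZT6, 2567 for CT12 against ZT12, 1429 for the hour, 1030 for CT against ZT and 1368 for the difference between time effects. The weight estimate did not converge; it gave CT12 array 2 a weight of 48.5 and CT12 array 1 a weight of 0.0439, so that the CT12 group rests nearly on 1 array, and these counts are not a measure of the biology. The title number as a replicate block gave 8 for CT12 against ZT12, 7 for the hour and 2 for the difference between time effects, and it ended 18 of the 28 calls of named genes. Whether the number marks a batch stays open. Arrays with the same number had a mean r of 0.05 after removal of group means, against -0.02 for the others, and 5 of 12 arrays correlated best with their own number, but number 3 has its own source name.

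Leaving out all arrays numbered 3 gave 0 for ZT12 against ZT6 (313 at an unadjusted p under 0.05), 1 for CT12 against CT6, 1 for CT12 against ZT12, 0 for the hour (716) and 3 for the difference between time effects, with fewer samples. The 6 arrays compared alone gave 87 for ZT12 against ZT6, 0 for CT12 against CT6 (578) and 0 for CT12 against ZT12 (690). These are the directions in which a spread shared with the wider CT12 group shifts p. Fewer arrays and a new normalization and filter also entered, and their parts were not separated. The lens covariate gave 3 for ZT12 against ZT6, 0 for CT12 against CT6 (464), 2 for CT12 against ZT12 and 0 for the hour (265). Leaving out single arrays gave 1 to 79 for ZT12 against ZT6, 0 to 1302 for CT12 against CT6, 0 to 3 for CT6 against ZT6, 0 to 1069 for CT12 against ZT12, 3 to 176 for the hour, 0 to 3 for CT against ZT, 1 to 62 for the difference between time effects and 3703 to 4244 for tissue. The highest counts without an array were those without CT12 array 3 (1302, 1069, 176 and 62) and without CT12 array 1 (79 for ZT12 against ZT6, 4244 for tissue). Without CT12 array 3 the group held arrays 1 and 2, the arrays highest in lens genes (17.17 and 17.02, against 15.53 on array 3). The counts without array 3 were therefore not separated from the lens level. Where an array was left out of 3, the remaining ones were assumed to vary like the other groups.

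Of the lists that passed with the preset correlation, 0 passed with an estimated one in each of the 8 comparisons. The mean of all probe sets per gene gave 3 lists for the hour, where the main count was 5, and 6 for tissue, where it was 3. Without CT12 array 1 the lists that passed were 5 for ZT12 against ZT6, 7 for CT12 against CT6, 1 for CT6 against ZT6, 6 for CT12 against ZT12, 4 for the hour, 5 for CT against ZT and 2 for the difference between time effects, in place of 6, 6, 1, 9, 5, 7 and 5.

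Among named genes past the threshold in the retina, the direction and the call held in 307 combinations of gene, comparison and setting, and the call was lost in 226. Of those not past it, 2071 kept both, 174 gained a call and 33 reversed. In the tissue comparison 971 kept and 1 lost the call. Fos at ZT12 against ZT6 passed in 18 of 19 settings, with differences from 1.81 to 2.02 and adjusted p from 1.94e-05 to 0.0685; Egr1 passed in 14 of 19, with differences of 5.47 to 5.85.

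Reversals concerned genes near 0 or with a wide spread, none past the threshold in the main comparison. As deposited, Maoa was -0.06 at CT12 against CT6 and Tef -0.08 for the hour; at a common median Maoa was -0.07, Tef -0.05 and Csnk1d 0.02 at ZT12 against ZT6. With array weights Maob was 0.02 at ZT12 against ZT6, and at CT12 against CT6 Hlf was -0.05 and Rorb 0.95. Without the arrays numbered 3 Csnk1d was 0.13 and Gch1 0.07 at ZT12 against ZT6, and Tef -0.03 for the hour. The 6 arrays alone gave 0.00 for Csnk1d. With the lens covariate Nr1d2 and Bmal1 were 0.01, Csnk1d 0.00, Maob 0.08 and Gch1 0.07 at ZT12 against ZT6, and Nr1d2 0.04 at CT12 against CT6 and 0.03 for the hour.

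With single arrays left out, Tef ranged from -0.04 to 0.06 for the hour, and at ZT12 against ZT6 Maob ranged from -0.13 to 0.14, Csnk1d from -0.06 to 0.08 and Gch1 from -0.08 to 0.07. At CT12 against CT6 Maoa ranged from -0.06 to 0.25 and Rorb from -1.12 to 1.11, the latter without CT12 array 1 (adjusted p = 0.0928). For pineal against retina Bmal1 ranged from -0.36 to 0.12 and Rorb from -0.16 to 0.65.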

Other observations

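In the single pineal arrays, blood genes were lower at hour 12 under both regimes, with a median difference of -1.44 log2 units under Zeitgeber time and -1.21 under circadian time. Chaperone genes had medians of 0.23 and 0.47, and oxidative phosphorylation genes of -0.18 and -0.15. Ribosomal protein genes stood at -0.11 and -0.31, and immediate early genes at 0.28 and 0.21. Dopamine signalling genes went from -0.22 to 0.37 between the regimes, and glucocorticoid-responsive genes from 0.48 to -0.39. These are differences between 1 array and 1 array, with no test.

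The pineal array titled ZT12 carries an hour of 6 in its description. Its Aanat intensity was 12652, where the arrays at hour 6 had 579 and 432 and the CT12 array had 20036. Its Slc15a1 intensity was 4362, against 40 and 19 at hour 6 and 8888 at CT12. The title was kept for every comparison except 1 alternative of the tissue comparison, in which hour 6 was used.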
